A study of Drosophila melanogaster with 3 samples.

How the data were processed

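The series holds putzig-eGFP ChIP-seq from whole Drosophila melanogaster embryos of both sexes, 0 to 24 h old, in 3 biological replicates of 1 group. Group and target were taken from the antibody field and replicate numbers from the library descriptions. Those descriptions also call each library an input control, a conflict with the assay and antibody fields that the labels do not resolve. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. Coordinates are dm6, per the deposited notes, and positions are given 1-based.

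The authors deposited 5 peak lists: 1 per replicate, 1 from the pooled replicates and 1 reproducible list thresholded by the irreproducible discovery rate (IDR). Each replicate's peaks were derived from its own alignment and from a control alignment shared by the replicates, per the deposited notes. The aligner, the peak caller and their versions are not given in the sources used here. The replicate and pooled lists hold 30000 entries each and include background by design, so list length says nothing about the number of sites. In all lists the signal column holds the deposited peak signal of the authors' caller, whose scale is not named, and it was used only within a list, to rank peaks and for ratios of medians or percentiles, which assume nothing on how signal relates to the number of reads and cannot be read as ratios of reads. The deposited −log10 q value reaches a ceiling, 4.12 in the reproducible list, which all its peaks share, so it was not used for ranking. The 6522 reproducible entries were checked to be the 6522 strongest of the pooled list. They are therefore not independent of the replicates, whose reads the pooled list contains. Read depth, and with it counting error per peak, is unknown, so precision was taken from the spread over the replicates' own 6522 strongest peaks. The common list length limits how far counts, such as bound genes, can differ between replicates. In the reproducible list 413 intervals carry more than 1 summit, and each summit was kept as an entry.

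Genes and TSSs came from the Ensembl annotation of the same assembly, without transposable elements, and sequence from the RefSeq genome. Of 30593 annotated start codons, 99.8% read ATG in that genome, and no peak passed a chromosome end. A TSS was called bound when a summit lay within 250 bp, and a gene when any of its TSSs was bound. A replicate was said to hold a reproducible peak when its summit lay inside one of that replicate's 6522 strongest peaks. Expected overlap and location came from 1000 within-chromosome shuffles (100 for exons, introns and intergenic sequence). Gene lists, divergent promoters (opposite-strand TSSs within 500 bp) and chromosomes were compared with two-sided Fisher's exact tests against all other protein-coding genes of the chromosomes covered, with Benjamini-Hochberg adjustment over the 25 lists at 0.05. Odds ratios have 0.5 added to each cell, and intervals are 95%. Genes tested together share peaks and neighbours, so these p-values describe the list, not new embryos. Motifs and 8-mers were counted once per window, 100 bp to each side of the summit, on either strand, against windows shifted by 1000 bp to both sides, and each motif was set beside its reversed sequence, except GAGAGAG, which reads the same reversed. Signal at TSSs and elsewhere was compared by a two-sided permutation test of the ratio of medians with 100000 resamples. Binomial intervals are Wilson's and cover counting error only. For a list with 0 bound genes a counting limit of 3 genes of the list is given. All members of each list were examined, so this limit does not measure what the cut of the peak list could miss.

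The groups, tests, gene lists, motifs, rule for named genes and most alternatives were fixed before the data were examined. The rule took the genes at the 10 strongest peaks, up to 4 bound members of each list by signal, 12 genes fixed by name (pzg, Dref, Trf2, Iswi, E(bx), Chro, BEAF-32, Cp190, PCNA, N, EcR and Stat92E) and the 10 8-mers with the lowest p. Genes named as unbound, such as su(Hw) and the Hsp70 genes, were chosen after their values were seen. The test on chromosome 4 was also chosen after its values were seen. Every listed symbol matched a gene, some through older symbols. Alternatives covered the peak set, the TSS window and assignment, the gene background, the motif window and background, and the divergent distance. They also covered the reproducible peaks found in each pair of replicates, which still come from the pooled list of all replicates. The functions were tested on simulated data: 87.5% of 200 simulated lists of 20 or more genes with an odds ratio of 4 or 0.25 were called in the right direction, and 5 of 240 lists with no effect were called. No 8-mer of 32895 was called between random groups of flanking windows, and an 8-mer planted in 5% of windows ranked first. Both groups were drawn from the same flanking windows, so this does not test for differences in base composition between summit and shifted windows. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.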

Results

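The data collected were genome-wide maps of where putzig (pzg) sits on chromatin in whole Drosophila melanogaster embryos. Putzig is a zinc finger protein known from a complex with the core promoter factor Trf2 and the transcription factor Dref, and from the nucleosome remodelling complex NURF. Embryos of both sexes, 0 to 24 h old, carried putzig fused to eGFP, and the tagged protein was recovered by chromatin immunoprecipitation and sequenced (ChIP-seq). The 3 samples are biological replicates of 1 group, so the design holds no contrast between conditions. The free-text description of each library calls it an input control, whereas the assay field and the antibody field name putzig ChIP-seq, and the deposited notes derive each replicate's peaks from its own alignment and a separate control alignment. The samples were treated here as putzig ChIP-seq. The values of a peak list carry no read depth, so the depth of each library is unknown here. The reproducible list held 6522 summits in 6098 distinct intervals, with a median interval width of 424 bp. Each replicate's own list held 30000 summits, a ranked set that includes background, and the strongest 6522 of each gave the spread between replicates.

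Most putzig peaks recurred in all replicates. Of the 6522 reproducible summits, 5253 (80.5%) lay inside one of the strongest peaks of every replicate, and 26 lay in none. Shuffling the summits within their chromosomes gave 59.1 shared summits on average, and the observed number passed the highest of 1000 shuffles (permutation p = 0.001, the smallest they can give). The summits were called from these replicates' pooled reads and kept by the IDR threshold. This outcome was therefore fixed in advance, and the p does not test agreement. Replicates 1 and 2 held 95.7% and 95.4% of the summits, and replicate 3 held 84.9%. Peak signals were correlated between replicates, with Spearman's rho of 0.96 between replicates 1 and 2, 0.86 between 1 and 3, and 0.86 between 2 and 3. These rho are across peaks, which are not independent replicates. They cover only the 6458, 6011 and 6013 reproducible summits that lay in a peak of any strength in both replicates. Summits missing from either replicate were left out, so agreement over all summits would be lower or unknown. Of the 1305 strongest peaks 99.2% were found in all replicates, and of the 1304 weakest 30.4%. Among the 6522 strongest peaks the highest q value was 0.0105 in replicate 3 and 0.000387 in replicate 1. In replicate 2 it was 5.62e-05, the ceiling of its q values, which all these peaks share. The share was 46.5% when peak intervals had to overlap by 50% of each, 88.1% with 1 bp of overlap, 91.8% with all peaks of each replicate, and 98.2% for the reproducible peaks above the median signal.

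**Figure D1:**
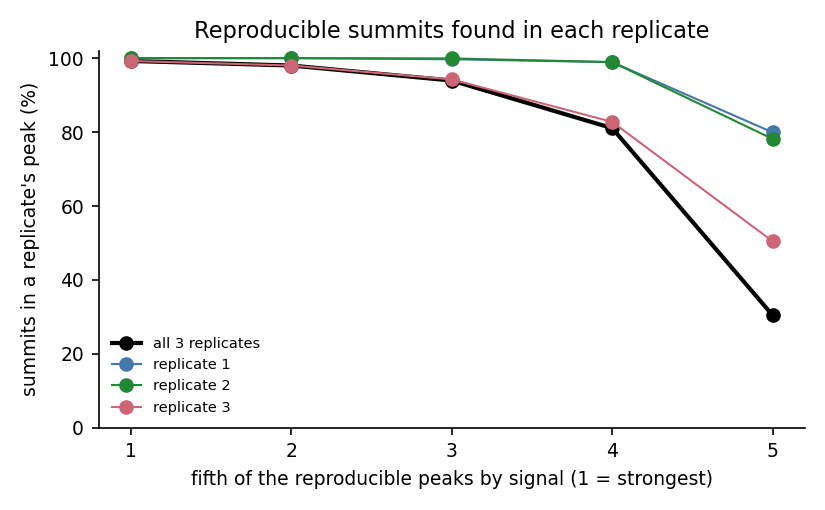
Share of reproducible summits (y axis, %) that lay in one of the strongest peaks of each replicate (coloured) or of all 3 (black), in 5 groups by signal rank (x axis, 1 strongest). The share in all 3 fell from 99.2% to 30.4%, and replicate 3 held 50.5% of the weakest group.

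Putzig sat at gene starts. Of the reproducible summits, 5486 (84.1%) lay within 250 bp of an annotated transcription start site (TSS), 11.2 times the 7.50% of shuffled summits (permutation p = 0.001, the smallest 1000 shuffles can give). The share was 83.5% ± 2.33 (SD, n = 3) over the replicates. The median summit at a TSS was 33 bp upstream of it, and 79.6% of these summits lay upstream. Introns away from a TSS held 7.27% of summits against 41.3% of shuffled ones, intergenic sequence held 6.52% against 28.3%, and coding exons held 0.429% against 15.9%. The strongest peak of the genome, on chromosome 3R from 12627557 to 12628276 (dm6), stood between Vha55, a subunit of the vacuolar proton pump, and Snx3, a sorting nexin. The next peaks stood at the TSSs of BTBD9 and Atg8a, an autophagy protein (X, 10767940 to 10768814), of the ribosomal protein gene RpL30 (2L, 19009001 to 19009674), of ATPsynF and CG3548 (2R, 24599521 to 24600193) and of RpL23A (3L, 1668433 to 1669030). Ranks 6 to 10 fell at Abl, NAT1, Galphai, the pair fs(1)h and mys, and Sar1. None of these 10 summits lay inside a gene body, and each ranked among the 12 strongest peaks of every replicate. Peaks at a TSS were also stronger, with a median signal of 1245 against 428 elsewhere, a ratio of 2.91 (two-sided permutation p = 1e-05, the smallest 100000 resamples can give). The ratio was 2.73 ± 0.194 (SD, n = 3) over the replicates, and 1.23 among the peaks above the median signal.

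**Figure D2:**
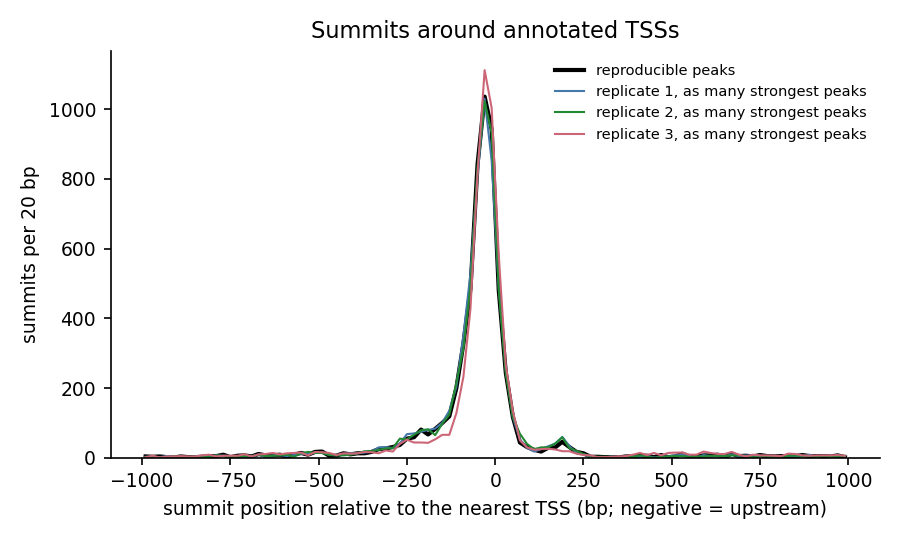
Number of summits per 20 bp (y axis) by position relative to the nearest annotated TSS (x axis, bp, negative upstream), for the reproducible list (black) and for the same number of strongest peaks of each replicate (coloured). The summits at a TSS have their median 33 bp upstream in the reproducible list and 28 bp upstream in replicate 3.

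A large minority of the protein-coding genes carried putzig at a start site: 5939 of 13945 (42.6%), with 5874 ± 49.9 (SD, n = 3) over the replicates and 5473 bound in all of them. Each replicate's list was cut to the same length, which limits this SD. At a q value of 0.05 or less, replicates 1, 2 and 3 held 9150, 15916 and 7788 entries. Among genes of other classes, whose difference from protein-coding genes was not tested, putzig was at 174 of 3261 ncRNA genes (5.34%), 10 of 290 tRNA genes, 12 of 269 snoRNA genes, 4 of 32 snRNA genes and 0 of 99 rRNA genes. The rRNA genes are repeats, at which reads could be split or dropped, so their 0 is uncertain. The peaks above the median signal reached 3950 protein-coding genes.

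Genes of basic cell functions were bound far more often than the rest. Of 25 gene lists, 9 were more often bound than all other protein-coding genes, at an adjusted p under the threshold of 0.05 (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). Among 26 chromatin and insulator genes, many of them known partners of putzig, 25 were bound (log2 odds ratio 4.52, adjusted exact p = 2.2e-08), and su(Hw) was the exception. The mitochondrial ribosomal protein genes were bound in 69 of 73 cases (log2 odds ratio 4.40, adjusted exact p = 1.3e-20), led by mRpL47 with a signal of 8558. The cytosolic ribosomal protein genes followed with 85 of 93 (log2 odds ratio 3.78, adjusted exact p = 1.8e-22), and RpL30, RpL23A, RpL7 and RpL41 had signals of 12112, 11348, 10822 and 9248. DNA replication genes were bound in 43 of 47 cases (log2 odds ratio 3.71, adjusted exact p = 7.9e-12), among them Top2, the origin licensing factor dup, Orc5 and PolA2 with signals of 4949, 4801, 4660 and 4229. Aminoacyl-tRNA synthetase genes were bound in 30 of 33 cases (log2 odds ratio 3.56, adjusted exact p = 2.2e-08), including GlnRS and TrpRS, and spliceosome genes in 29 of 33 (log2 odds ratio 3.15, adjusted exact p = 2.0e-07), including snRNP-U1-70K and SmD3. Of 51 cell cycle genes 42 were bound (log2 odds ratio 2.60, adjusted exact p = 2.7e-08), with CycB, the centrosomal gene cnn, Dp and the spindle checkpoint gene mad2 at signals of 7276, 6693, 6269 and 5868. Oxidative phosphorylation genes were bound in 58 of 80 cases (log2 odds ratio 1.82, adjusted exact p = 1.8e-07), led by ATPsynF and ATPsynC, and proteasome genes in 34 of 48 (log2 odds ratio 1.69, adjusted exact p = 0.000166), led by Prosbeta1. Each of these lists lay above the other genes in 3 of 3 replicates, and the lowest value of any replicate was 68.8%, for the proteasome in replicate 3. With the comparison limited to genes that have a peak of any strength at the TSS in all 3 replicates, 3 lists were more often bound, the cytosolic and mitochondrial ribosomal proteins and DNA replication. The other 6 missed the threshold there with log2 odds ratios of 1.18 to 3.16, against 1.69 to 4.52 among all genes.

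Several lists of tissue-specific genes were rarely bound in the reproducible list. Chromatin came from whole embryos of a wide age range, so binding in few cells or hours could fall below the cut of that list. This was not tested, and unbound here does not mean that putzig is absent in every cell. The 10 lists less often bound than other genes by Fisher's exact test included 0 of 117 cuticle protein genes (adjusted exact p = 5.9e-28, counting limit 2.56%). They also included 2 of 180 chemoreceptor genes, Ir76a and Gr61a, with weak peaks found in 1 and 2 replicates (log2 odds ratio -5.76, adjusted exact p = 5.1e-39). Cytochrome P450 genes were bound in 2 of 81 cases, Cyp6a22 and Cyp6u1 (log2 odds ratio -4.57, adjusted exact p = 3.3e-16). None of 27 trypsin and Jonah protease genes, 15 chorion and vitelline membrane genes, 14 antimicrobial peptide genes and 8 Hox genes was bound (adjusted exact p = 7.1e-07, 0.00044, 0.000761 and 0.0323). The counting limits were 11.1%, 20%, 21.4% and 37.5%. Of 24 segmentation genes only the maternal gene bcd was bound, 204 bp upstream of its TSS (adjusted exact p = 6.7e-05). Of 30 muscle structure genes 3 were bound, Tm1, Actn and Zasp52 (adjusted exact p = 0.000224), and the Actn summit is the one that also lies upstream of usp. None of the 111 genes of the histone cluster was bound (adjusted exact p = 1.4e-26), a value that stays uncertain because these copies are near identical and reads could be split between them or dropped. Each of the 10 lists lay below the other genes in 3 of 3 replicates. The Hox list missed the threshold with a TSS window of 100 bp (adjusted exact p = 0.0751), with the nearest TSS only (0.0717) and among the peaks above the median signal (0.131). Limited to genes with a peak of any strength in all 3 replicates, 5 lists were less often bound, the cuticle, protease, P450, segmentation and neuron genes, and the muscle and chemoreceptor genes missed the threshold with log2 odds ratios of -2.91 and -2.17. The Hox, antimicrobial peptide, chorion and histone lists were not tested there.

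Genes of the signalling pathways tied to putzig did not pass the threshold as lists. The Notch pathway had 18 of 30 genes bound (log2 odds ratio 1.00, adjusted exact p = 0.0764), with the ubiquitin ligase genes Su(dx) and mib1, the corepressor gro and N itself at signals of 7936, 6729, 4900 and 3288. The JAK/STAT pathway had 8 of 13 (adjusted exact p = 0.284), led by Socs36E at 8366 and dome at 4103, and the ecdysone pathway 8 of 24 (adjusted exact p = 0.431), led by Hr39 at 4828 and ftz-f1 at 3012. Germline and piRNA genes were bound in 13 of 22 cases (adjusted exact p = 0.152), heat shock protein genes in 8 of 19 (adjusted exact p = 1), and neuron genes in 8 of 32 (adjusted exact p = 0.0613). Among the heat shock genes the bound ones were led by the constitutive Hsc70-4 and by Hsp83, and all 6 Hsp70 genes were unbound, which stays uncertain because these copies are alike and reads could be split between them or dropped. Alternatives moved 3 of these lists past the threshold. The neuron list was less often bound among peaks found in replicates 1 and 3 (adjusted exact p = 0.0236) and in replicates 1 and 2 (0.0142). The same held among peaks above the median signal (0.00463) and among peaks found in all 3 replicates (0.0244). It also held with the 5′ end of each gene only (0.0149) and against genes with a peak of any strength (0.00359). The highest value of the neuron list over the alternatives was 0.713. The Notch pathway was more often bound among peaks found in replicates 1 and 2 (adjusted exact p = 0.0498). It also was with the nearest TSS only (0.0156) and with the 5′ end only (0.0467), with 0.349 as its highest value. Germline genes were more often bound with TSS windows of 500 bp (adjusted exact p = 0.0218) and 1000 bp (0.0400), with 0.847 as their highest value.

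**Figure D3:**
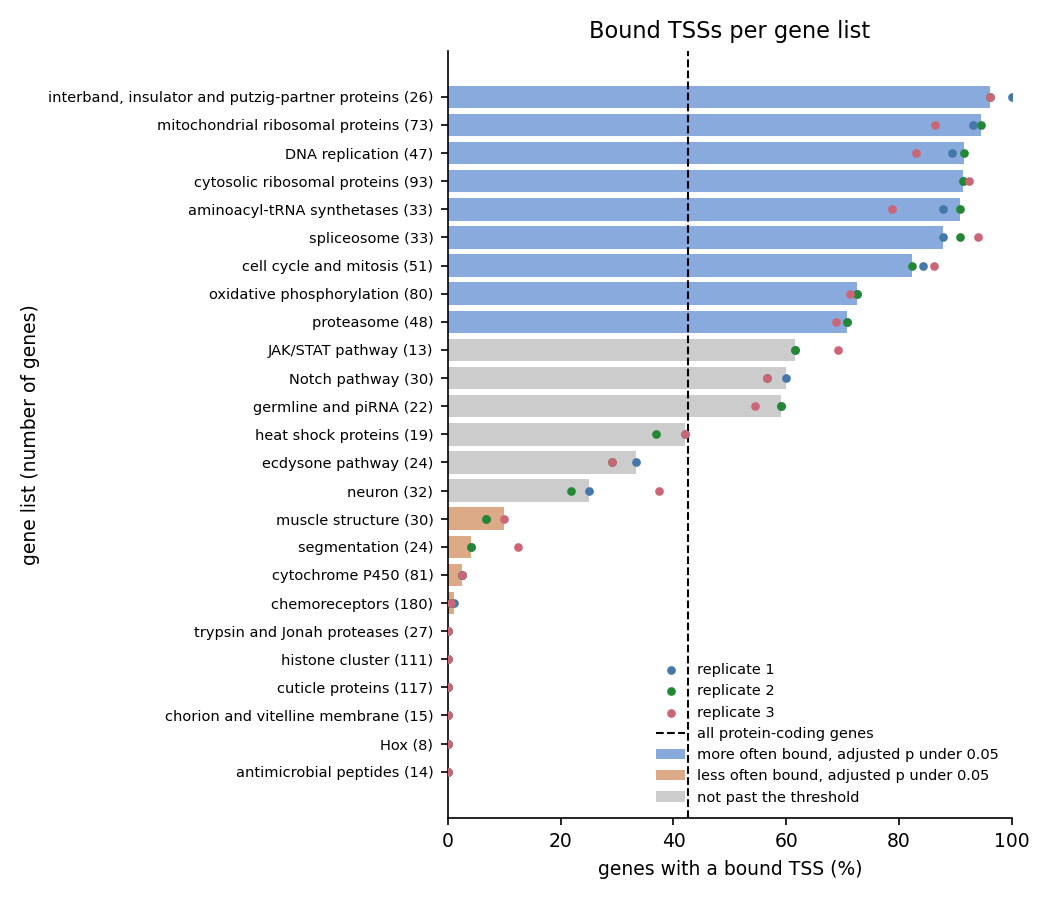
Share of the genes of each list with a bound TSS (x axis, %), with the number of genes in brackets. Bars are the reproducible list, coloured by the test, points are the 3 replicates, and the dashed line is the 42.6% of all protein-coding genes.

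Putzig bound its own gene and those of its partners, as it did 42.6% of all protein-coding genes. The pzg peak (3L, 21285543 to 21286461) had its summit 89 bp upstream of the TSS and a signal of 4604. E(bx) and Iswi, both NURF subunits, had signals of 3566 and 3488, Dref 2457, Chro 2203, Cp190 2155, Trf2 1771 and BEAF-32 951. PCNA, a replication gene known for its DRE promoter, carried a peak of signal 1316 (2R, 20262721 to 20263089) and Stat92E one of 1714. Bound genes outside the chromatin and insulator list had a median signal of 1517, above the values of BEAF-32 and PCNA. The summit windows of PCNA, Iswi and Cp190 held 1 DRE each, and those of the other bound genes named here held 0. The Dref and Chro summits lay in the 5′ UTR, the Stat92E summit lay in an intron 26 bp upstream of an internal TSS, and the others lay upstream of the gene. Each of these summits was found in all 3 replicates. EcR, the ecdysone receptor gene, had no reproducible summit within 250 bp of any TSS.

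The DNA replication-related element (DRE), TATCGATA, the site that Dref recognises, was enriched at putzig peaks. It occurred in 944 of 6522 summit windows, 100 bp to each side of the summit (14.5%) and in 0.636% of windows shifted by 1000 bp, a log2 odds ratio of 4.72 (95% interval 4.39 to 5.04). The replicates gave 14.4% ± 0.307 (SD, n = 3). The reversed sequence ATAGCTAT, made of the same bases, was in 0.659% against 0.192% (log2 odds ratio 1.78, 95% interval 1.07 to 2.48). The DRE share was 21.8% in the 1305 strongest peaks and 4.98% in the 1304 weakest, and 16.2% at TSSs against 5.60% elsewhere. The share of peaks at a TSS fell over the same ranks, from 97.0% to 59.9%. Of the 1387 DREs of the genome within 250 bp of a TSS, 70.3% had a summit within 100 bp, and of the 2632 elsewhere 2.62% did. For the reversed sequence these shares were 20.6% of 170 sites and 0.443% of 1807, so the contrast by location is not particular to the DRE. Motif 1, GGTCACAC, another element of housekeeping promoters, was in 12.7% of summit windows against 0.644% (log2 odds ratio 4.48, 95% interval 4.16 to 4.81). Its reversed sequence CACACTGG was in 3.20% against 0.705%. On the other strand CACACTGG overlaps CAGTGTGA, which itself overlaps Motif 1 and was in 7.28% against 0.560%. The rise of CACACTGG therefore cannot be told apart from that of Motif 1, and it is no separate control. CGATA, the core of the BEAF-32 site and part of the DRE, was in 51.6% against 22.9%. Its reversed sequence ATAGC was in 31.6% against 23.7%. The other strand of GCTATCGA, in 6.49% against 0.575%, holds both CGATA and ATAGC. ATAGC is therefore no separate control, and its rise does not show that the rise of CGATA is unspecific. The E-box CAGCTG was in 18.6% against 11.4%, and its reversed sequence GTCGAC was rarer at summits, 1.89% against 2.67%. The site CAGGTAG of the early embryonic activator Zelda was rarer at summits, 0.690% against 1.52% (log2 odds ratio -1.14, 95% interval -1.60 to -0.67), but its reversed sequence GATGGAC was rarer too, 1.44% against 2.23% (log2 odds ratio -0.64, 95% interval -0.97 to -0.30), and the intervals overlap. TATAAAA was in 11.6% against 7.36%, but its reversed sequence rose more, 21.4% against 10.8%. The insulator site AGGTGGCG was in 1.32% against 0.744%, GAGAGAG in 3.43% against 2.89% and Motif 7, CAGCGCTA, in 0.552% against 0.345%. The reversed sequences of the insulator site and of Motif 7 were not enriched, at 0.368% against 0.974% and 0.322% against 0.437%.

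**Figure D4:**
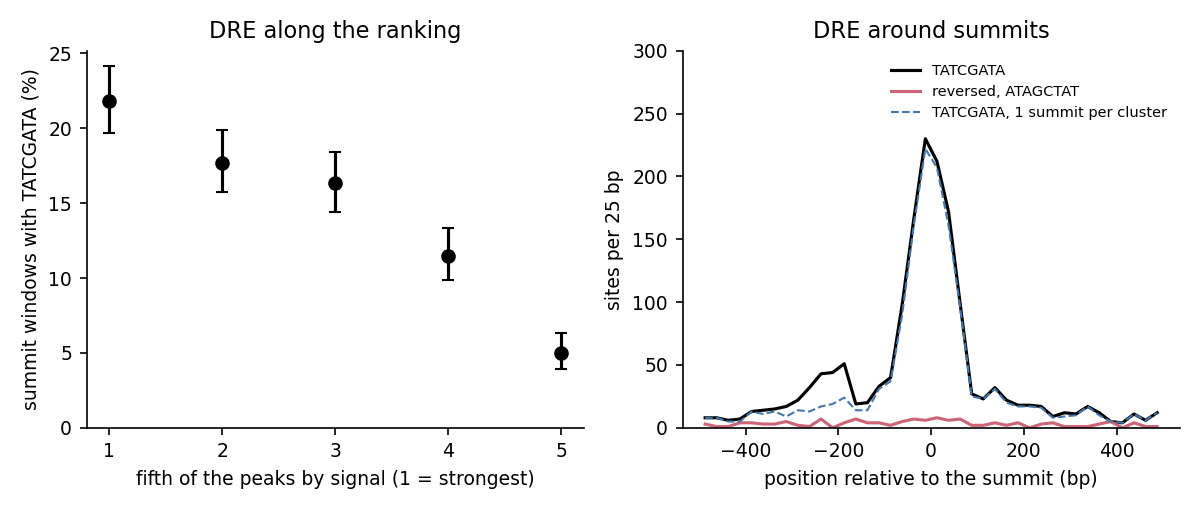
Left, share of summit windows with TATCGATA (y axis, %) in 5 groups by signal rank (x axis), with 95% Wilson intervals that cover counting error only, from 21.8% in the strongest to 4.98% in the weakest. Right, number of sites per 25 bp (y axis) by position relative to the summit (x axis, bp, genome orientation) for TATCGATA, its reversed sequence, and TATCGATA around the strongest summit of each cluster. Of the TATCGATA sites within 500 bp of a summit, 48.2% lie within 50 bp.

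A search over all 8-mers gave the same sequences without a list. Of 32896 8-mers, 3774 were more frequent and 6382 less frequent in summit windows than in shifted windows (two-sided Fisher's exact test, adjusted p under 0.05). The pair with the lowest p was TATCGATA and GGTCACAC. Of the next 8, 6 overlap the DRE or its flanks (ATCGATAG, ATCGATAA, ATATCGAT, GTTATCGA, AATCGATA and ACTATCGA, in 7.01% to 13.3% of windows), and AGTGTGAC and CAGTGTGA overlap Motif 1 (10.5% and 7.28%). With windows of 50 bp to each side, 1923 8-mers were more frequent.

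Genes with an opposite-strand TSS nearby were bound more often. That TSS could belong to a gene of any class and lie to either side, so overlapping starts were counted too. Of 4299 protein-coding genes with a TSS on the opposite strand within 500 bp, 73.4% were bound, against 28.9% of the other 9646 (log2 odds ratio 2.76, 95% interval 2.65 to 2.88). Over the replicates it was 2.75 ± 0.09 (SD, n = 3). A summit near such a pair of TSSs counts for both genes. With each summit given to its nearest TSS only, the log2 odds ratio was 1.46.

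X-linked genes were bound slightly more often than autosomal ones, 1038 of 2196 (47.3%) against 4854 of 11669 (41.6%), with a log2 odds ratio of 0.33 (95% interval 0.20 to 0.46, two-sided Fisher's exact p = 9.7e-07). Over the replicates it was 0.30 ± 0.02 (SD, n = 3). Among the peaks above the median signal the log2 odds ratio was -0.039 (exact p = 0.606), and the median signal of X peaks was 871 against 1125 on the 4 large autosomal arms. On the small chromosome 4, 47 of 80 genes were bound (58.8%, exact p = 0.00285 against the autosomes, a test chosen after the value was seen). This rested on replicates 1 and 2, with 62.5% and 61.3% bound, whereas replicate 3 had 35.0% (log2 odds ratio -0.36 against its autosomal genes, exact p = 0.306).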

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

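The tests on the next summits of the pooled list and on the X copy ratio were chosen after their results were seen, and for chromosome 4 and the 90th percentile the criteria were made stricter, and the matching on GC content corrected for tied values, after first results were seen, and the GC contents of chromosome 4 and replicate 3 were known before. The next 6522 summits of the pooled list, which no comparison above uses, still carried a signal at gene starts. Of them, 29.2% lay within 250 bp of a TSS, against 7.51% of shuffled ones (permutation p = 0.001, the smallest 1000 shuffles can give). Summits near TSSs already bound were not removed. Only 10299 of the 30000 pooled entries had a q value of 0.05 or less, so these summits include background. Of these summits, 6.15%, 6.65% and 9.03% lay in the strongest peaks of replicates 1, 2 and 3. The DRE was in 0.981% of the windows of these summits and in 0.966% of shifted ones (log2 odds ratio 0.028, 95% interval -0.41 to 0.46). They gave a summit to 991 of the 8006 genes without a reproducible one, and neuron genes were the 1 list over-represented among these, 9 of 24 against 12.3% (Fisher's exact test, adjusted p = 0.00977). Chemoreceptors (2 of 178), the histone cluster (0 of 111) and cuticle protein genes (4 of 117) were under-represented (Fisher's exact test, adjusted p = 6.6e-07, 7.9e-06 and 0.00977).

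Peaks at gene starts, rich in the DRE, were set against 3 explanations. Base composition is argued against, since the lower bound of the DRE log2 odds ratio, 4.39, lies above the upper bound of the reversed sequence, 2.48. Signal that follows transcription stays open: bound ribosomal protein genes, among the most transcribed, had 1.76 times the median signal of other bound genes, on a scale that is not named (two-sided permutation p = 1e-05, the smallest the resamples can give). Signal at any open housekeeping promoter cannot be told apart from binding through the DRE, because no measure of open chromatin was used: TSS windows with the DRE and not Motif 1 were bound in 86.6% of cases and those with Motif 1 and not the DRE in 91.4% (log2 odds ratio -0.71, 95% interval -1.12 to -0.31), against 29.1% with neither. No biological explanation was tested, as the design has 1 group.

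Chromosome 4 peaks were missed in replicate 3, which held 39 of 64 (60.9%, 95% Wilson interval 48.7% to 71.9%), whereas replicates 1 and 2 held 63 and 64. The shortfall was not limited to strong peaks. Among the entries of replicate 3 beyond its strongest, density on chromosome 4 was 0.147 times that of the autosomes. In replicates 1 and 2 it was 0.529 and 0.409 times. Loss of AT-rich fragments is argued against as the whole cause: autosomal peaks matched on GC content were found in 82.1% of cases (95% interval 78.0% to 85.5%). So is low signal in a weaker library, with 88.05% of signal-matched peaks found, and both together, with 85.7%. Within autosomes, replicate 3 did hold fewer of the 1048 peaks with the lowest GC content, 74.0% against 88.8% of the next 1047. Composition over wider regions and a difference in the embryos of that replicate may contribute and were not tested, nor was any biological explanation.

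Peaks at X-linked TSSs had 0.819 times the median signal of autosomal ones (95% bootstrap interval 0.755 to 0.879). An X copy ratio of 0.75, for as many males as females, lies just outside this interval. It also lies below the intervals of replicates 1, 2 and 3, which start at 0.772, 0.780 and 0.799, with ratios of 0.829, 0.837 and 0.877. The bootstrap resampled peaks within each list, so these intervals do not cover variation between embryos. The scale of the signal is not named, however, so fewer X copies cannot be told apart from other causes. A larger share of weak X promoters could contribute: at the 90th percentile over bound and unbound genes the ratio was 0.938 (interval 0.864 to 1.01). The replicates keep this open, with intervals that end at 0.980, 1.01 and 1.06, and the end for replicate 2 is close enough to 1 to depend on the bootstrap draws. The sex ratio was not measured, and no biological explanation other than the copy ratio was tested.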

How the results depend on the processing

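Of the alternatives, those with 1 summit per cluster of 250 bp, without genes that have a divergent neighbour and without the histone cluster were chosen after the data were seen. The TSS share (69.8% to 94.7%), the DRE log2 odds ratio (3.82 to 5.54), the divergent promoters (1.46 to 3.34), the TSS signal ratio (1.23 to 3.22) and the share found in all replicates (46.5% to 98.2%, or 42.4% with shortened replicate lists, which limit it by construction) kept their direction and side of the threshold in all alternatives run for them. For the share found in all replicates, the side of the threshold was fixed in advance by how the list was made. Among the reproducible peaks found in each pair of replicates, 5459 to 5761 genes were bound. These sets can only be smaller than the main one. Their peaks still come from the pooled list, so no replicate's reads were removed. Using only the peaks above the median signal left 3950 bound genes against 5939, from fewer peaks, and turned the X difference to a log2 odds ratio of -0.039, for which the cause was not tested. With genes that have a peak in all 3 replicates as background, 3 lists were more often bound against 9 and 5 less often against 10, with fewer genes tested. Of those 10, 4 were less often bound there, 2 missed the threshold and 4 were not tested, and the neuron list was a further call. In windows of 50 bp to each side 1923 8-mers were more frequent against 3774, and shorter windows hold fewer sites. For single lists, 274 planned values kept their call, 11 gained one and 11 lost one, and of those added 72 kept it and 2 lost it, Hox and the proteasome without divergent neighbours. The strongest peaks of the pooled list and the 6 arms alone are the reproducible list itself, so they test nothing. Unknown depth limits what the weakest peaks can show.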

Other observations

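All tests in this part were chosen after the data were seen. The 1036 reproducible summits away from any TSS carried a sequence that was rare at gene starts. The insulator site AGGTGGCG of CTCF was in 4.05% of their windows, against 0.820% of shifted windows and 0.802% of TSS summits (log2 odds ratio 2.39 against TSS summits, 95% interval 1.77 to 3.00). The 8-mers with the lowest p there were GCGCCACC, GATGGCGC and TGGCGCCA (Fisher's exact test, adjusted p = 1.5e-09 for each). GCGCCACC was in 4.34% against 0.483% of shifted windows, and the others were each in 4.05% against 0.386%. Over the replicates GCGCCACC was in 4.24% ± 0.557 (SD, n = 3). The sequences of gene starts were enriched there as well, the DRE in 5.60% against 1.01%, Motif 1 in 2.32% against 0.869% and CGATA in 34.0% against 24.1% of shifted windows. GAGAGAG, in 6.27%, was not past the threshold against the 4.73% of shifted windows (Fisher's exact test, adjusted p = 0.132). Of 32867 8-mers, 116 were more frequent than in shifted windows.

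Gene copies of basic complexes were mostly unbound. Of 37 genes whose symbol is that of another member of the proteasome, oxidative phosphorylation or ribosomal protein lists plus R, T, L or "-like", 7 were bound, against 170 of the other 184 members (92.4%). In the proteasome, 31 of 32 other members were bound and 3 of 16 copies, Prosbeta2R2, Rpt3R and Rpt6R. In oxidative phosphorylation these counts were 57 of 63 and 1 of 17, COX7AL. Among ribosomal proteins RpL7-like, RpL24-like and RpLP0-like were bound and RpL22-like was not. The rule misses other duplicates, and RpS28-like, RpL10Aa, RpL37-2, RpS10a and RpS19b, all unbound, count among the other members. The naming rule was written after the unbound members were seen, so no p is given.

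Summits that share an interval were placed unevenly. In 94.6% of 424 cases the weaker summit lay at the higher coordinate, a median of 206 bp and never less than 199 bp from the strongest. Replicates 1, 2 and 3 gave 387 of 394, 658 of 707 and 14 of 14. In the reproducible list 211 DREs lay 150 to 300 bp to the lower side of a summit and 96 to the higher side (68.7% lower), and around the strongest summit of each cluster 53.7% lay on the lower side. Genome orientation has no meaning for promoters of both strands, and with 1 summit per cluster the results rerun kept their side of the threshold or a count within 1.5 times.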
